A study of Arabidopsis thaliana with 18 samples.

How the data were processed

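Transcript levels were measured in whole Arabidopsis thaliana seedlings on 18 single-colour Agilent arrays, with 1 RNA sample on each array. The labels place the samples in 6 groups of 3. The parental line carries a GUS reporter driven by repeats of a nitrate-responsive element. Lines 14 and 7 come from that line and express NLP6-SUPRD, a chimeric repressor made of the nitrate-responsive transcription factor NLP6 and the repression domain of SUPERMAN (SUP). Per the labels, seeds were stratified for 3 days and seedlings grew for 3.5 days at 23 °C under continuous light in liquid medium with 2.5 mM ammonium succinate as the only nitrogen source. Seedlings were collected at 0 h, before the medium was changed, and at 1 h after the change to fresh medium with 10 mM KNO3. None of the samples analysed here received fresh medium without nitrate, so the effect of nitrate and the effect of the medium change were measured together. Labelled cRNA was made from 1000 ng of RNA. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. For line 14 at 1 h the sample titles number replicates 1 to 3, while another label field calls all 3 of them replicate 1. The titles were used, and whether these are 3 separate samples rests on them.

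The authors scanned the arrays and extracted them with Agilent Feature Extraction 9.1. Per the file headers, the scanner files hold intensity values in linear units, background-subtracted and detrended within each array, with surrogate values for dim spots, and not scaled between arrays. The mean pixel intensity of each spot and the median intensity of its local background are given, per the file headers, as unprocessed values. The quality flags of each spot, of unit other, mark in the deposited files whether a spot was a control, was well above background, was saturated or was an outlier in uniformity or against its replicate spots. The authors' deposited value table holds a signal, which was checked to be the processed intensity divided by the 75th percentile of all 45220 spots of the array, linear and not centred by gene. The comparisons started from the scanner files, and the value table served as an alternative.

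The log2 processed intensity was taken relative to the array's 75th percentile over the 43803 spots that are not controls. Flagged outlier spots were left out and spots of the same probe were averaged, giving 43603 probes. A locus was read for 39057 probes, from the systematic name for 38413 and from the gene name for 644. The other 4546 probes were tested apart from the genes. Each of the 29043 loci was represented by its brightest probe over the 18 arrays. Gene symbols and positions came from a RefSeq table of the TAIR10.1 assembly, in which 28608 of the loci were found. The genome sequence was not used here, so probes were not placed in exons or untranslated regions. A gene was tested if its probe was well above background on all 3 arrays of at least 1 group, which left 21619 genes. Between 69.8% and 75.1% of spots were well above background on each array, with at most 3 saturated and at most 23 flagged spots. For arrays, the number of arrays limits the precision. Replicate arrays correlated across genes with Pearson's r between 0.9905 and 0.9968; genes are not independent replicates.

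Differences were estimated with limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 6 groups over all 18 arrays, with 12 residual degrees of freedom, and 13 contrasts were moderated by eBayes. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Errors given after ± are standard errors from this model unless SD is written, with 3 arrays in each group. The contrasts were the nitrate response (1 h against 0 h) in each line, the difference of each line and of the mean of both lines from the parental response, the lines against the parental line at 0 h and at 1 h, and the response of line 7 minus that of line 14. Gene lists were tested with camera at a preset correlation of 0.01 for lists with at least 5 measured genes, adjusted over the lists of a contrast. The test was repeated with the correlation estimated for each list. The 24 lists held 354 genes, of which 332 were tested. Counts of list members were taken from the adjustment over all genes, and again adjusted over the list alone.

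The share of the parental response kept by a line was the sum of the line's responses over the sum of the parental responses, each multiplied by the sign of the parental change. To keep the choice of genes apart from the measurement, genes called with at least 2-fold change were chosen with 2 of the 3 parental replicate numbers and measured in the third, in turn. The range over the 3 turns is given. The line's values were means of all its arrays in every turn, so that this range holds only the spread of the parental arrays. A second range used only the line's arrays with the replicate number left out in that turn. Lines 14 and 7 share their parental arrays, which were not split between the lines. The correlation and covariance that shared arrays give by themselves were therefore taken from 20 simulations with unchanged groups. Their simulated spread was independent between genes and arrays. With no gene changed almost no calls can arise, so these simulations do not show how many shared calls the arrays add.

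Where a probe was well above background on no array of a group, the fold against that group was given as a bound. For this, the group's value on each array was set to the lowest level of any probe well above background on that array, or to the gene's own value where that was higher. No bound was set for differences of responses. The genes named in the text come from a rule: for each comparison, the 10 genes with the largest rise and the 10 with the largest fall among those called, without overlap between the arrays compared, and any member of the gene lists. Loci without a single gene identifier were left out by the rule, and where fewer genes passed, those that passed were used. For differences of responses, overlap was judged on 1 h minus 0 h values matched by replicate number, although the labels do not say that the numbers pair samples. Chance gives no overlap for 10% of unchanged genes at 3 against 3 arrays. That share was not worked out for the mean of both lines.

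The sample grouping, the comparisons, the gene lists, the named-gene rule and most alternatives were set before the data were examined. The alternatives were normexp background correction with an offset of 50, quantile and median scaling, other filters on dim probes, the mean of all probes of a gene, the deposited value table, eBayes with an intensity trend, a minimum of 2-fold, flagged spots kept, fits of the compared groups only, replicate and slide blocks, and leaving out replicates. Chosen after the data were seen were a fit without the line 7 arrays, a correction for probe GC content and signal in 20 bins of each, the gene-list test with a slide block, and the NLP list without NLP6.

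The files place the arrays on 5 slides. Slides 1, 2 and 3 each held 1 array of the parental line and of line 14 at both times. Line 7 was on slides 4 and 5, scanned on another day. Slide and line therefore cannot be told apart for line 7 against the parental line, whereas each nitrate response can be computed within slides. The labels do not say whether the replicate numbers pair the samples. In the parental line and line 14 the replicate number is also the slide number. Of 45 pairs of arrays with the same number in different groups, 14 had residuals correlated above 0.1, against 15 of 90 pairs with different numbers and 10 of 23 pairs on the same slide. Arrays were not paired in the model, and blocks for the replicate number and the slide were fitted as alternatives. The methods were tested on simulated data with 200 changed genes, built from the measured means and spreads; 84% of simulated 2-fold nitrate responses were recovered, with 3.23% false calls, as were 72% of simulated 2-fold response differences of both lines. The ratio of responses was recovered within 1 percentage point of a simulated 50%.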

Results

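The data were 18 arrays, 3 for each of 6 groups: the parental reporter line, line 14 and line 7, each at 0 h in ammonium medium and at 1 h after transfer to nitrate medium. The 75th percentile of the processed intensity was between 923 and 1564 on the arrays of the parental line and line 14. On the line 7 arrays it was between 1656 and 2038. Brightness before scaling therefore separated line 7 from the other lines, as did slide and scan day. In 21619 genes, group means were compared to ask how seedlings respond to nitrate, and how this response and the levels before it differ when NLP6-SUPRD is expressed. Along the first 3 principal components of the gene levels lay 48.4%, 18.7% and 12.4% of the variance. On the first component the line 7 arrays lay between 44.59 and 62.21, and all other arrays between -60.23 and 2.26. This largest axis thus set line 7 apart, where line, slide and scan day cannot be told apart.

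The NLP6 transgene was seen in both lines. NLP6 (AT1G64530, chromosome 1, 23959627 to 23963083 in TAIR10.1) was measured by a pair of 60-nt probes that share the 15 nt ATGATGTGCTTGTGA. The upstream of these probes read 0.48 ± 0.04 (SD, n = 3) in the parental line at 0 h, on the log2 scale relative to the array's 75th percentile. It read 3.46 ± 0.05 (SD, n = 3) in line 14, 7.91-fold higher (adjusted p = 2.57e-11), and 4.34 ± 0.12 (SD, n = 3) in line 7, 14.5-fold higher (adjusted p = 6.6e-13). At 1 h it was 22.04-fold higher in line 14 and 30.2-fold higher in line 7. After transfer to nitrate the upstream probe rose by 1.38 ± 0.08 in line 14 (adjusted p = 3.22e-08) and by 0.96 ± 0.08 in line 7 (adjusted p = 1.6e-06). In the parental line its change was -0.09 ± 0.08 (adjusted p = 0.513). The downstream probe read 0.82 ± 0.10 (SD, n = 3) in the parental line at 0 h and differed from it by 0.04 ± 0.06 in line 14 (adjusted p = 0.575) and by -0.17 ± 0.06 in line 7 (adjusted p = 0.0158). Its change after nitrate passed the test in no line, with adjusted p of 0.268, 0.299 and 0.645. The probe for SUP (AT3G23130), whose repression domain the transgene carries, was well above background on no parental array. At 0 h it was at least 954-fold higher in line 14 and at least 1692-fold higher in line 7.

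**Figure D1:**
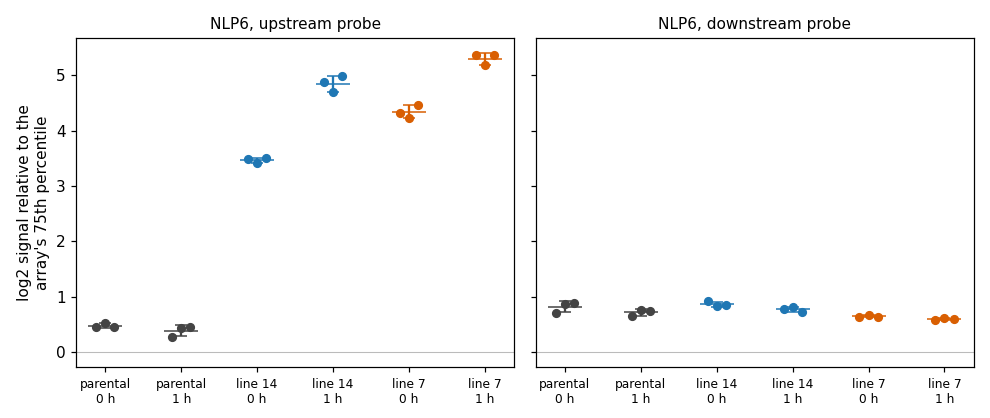
Log2 signal of the upstream and the downstream NLP6 probe relative to the array's 75th percentile, in the 3 lines at 0 h and 1 h. Points are single arrays and bars are the mean and SD of 3 arrays; the upstream probe rose from 3.46 to 4.85 in line 14 and from 4.34 to 5.30 in line 7.

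The parental line at 1 h was compared with 0 h to ask which transcripts change with the transfer to nitrate. The nitrate reductase gene NIA1 (AT1G77760) rose 33.0-fold (log2 5.04 ± 0.15), NIA2 (AT1G37130) 6.24-fold and the nitrite reductase gene NIR1 (AT2G15620) 27.2-fold (log2 4.77 ± 0.09). BT2 (AT3G48360), which encodes a BTB and TAZ domain protein, rose 45.4-fold (log2 5.50 ± 0.20), and the glutaredoxin gene GRXS7 (AT4G15670) 44.8-fold (log2 5.49 ± 0.19). UPM1 (AT5G40850), which encodes the methyltransferase of the sirohaem branch that supplies nitrite reductase with its cofactor, rose 22.4-fold (log2 4.49 ± 0.09). G6PD3 (AT1G24280), a plastid glucose-6-phosphate dehydrogenase gene, rose 24.8-fold (log2 4.63 ± 0.08). The adjusted p of these 7 genes was 5.96e-07 or lower.

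In this comparison limma called 4698 genes, 2195 higher and 2503 lower at 1 h, of which 338 were at least 2-fold higher and 269 at least 2-fold lower. With median scaling more genes were higher (2592) than lower (2065). The other genes with the largest rises included AT2G21210 and AT4G34790, both described as auxin-responsive, at 69.4-fold and at least 13.5-fold. AT2G21210 was well above background on 1 of 3 arrays at 0 h. AT2G36540 rose at least 32.0-fold, AT1G49500 32.2-fold, the mitochondrial carrier family gene AT5G26200 29.1-fold and SAG21 (AT4G02380), a late embryogenesis abundant family gene, 25.4-fold. The largest falls included AT1G64590, a short-chain dehydrogenase family gene (log2 -3.88 ± 0.12), AT4G26950 (log2 -3.71 ± 0.34), the cation exchanger gene CAX7 (AT5G17860, log2 -3.19 ± 0.11) and AHP4 (AT3G16360, log2 -2.58 ± 0.25), a phosphotransfer protein of cytokinin signalling. In each of these genes the 3 arrays at 1 h did not overlap the 3 at 0 h, which chance gives for 10% of unchanged genes. The rule for naming genes required this, so that it adds no support. With slide as a block, limma called 4758 genes. On slides 1, 2 and 3, with 1 array per group on each, the median log2 change of the nitrate regulators was 1.28, 1.31 and 1.37.

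Of the 21 regulators of nitrate signalling, 17 rose and 4 did not pass (adjusted over the list alone, 18 rose, list adjusted p = 1.49e-21). Among them were the protein kinase gene CIPK3 (AT2G26980, 14.5-fold, log2 3.86 ± 0.10), the LOB-domain genes LBD37 (6.10-fold) and LBD39 (AT4G37540, 4.62-fold, log2 2.21 ± 0.08), and NIGT1.3 (AT3G25790, at least 3.16-fold), which encodes a repressor and was well above background at 1 h but on no array at 0 h. Of 21 genes of nitrate uptake and reduction, 14 rose, 2 fell and 5 did not pass (adjusted over the list alone, 14 rose and 3 fell, list adjusted p = 6.23e-13). The nitrate transporter genes NRT2.1 (9.39-fold), NRT2.6 (23.8-fold) and NRT3.1 (3.99-fold) rose, as did the nitrite transporter gene NITR2;1 (AT5G62720, 12.4-fold), whereas NRT2.5 fell at least 2.02-fold. Of 23 genes of the pentose phosphate pathway and ferredoxin reduction, 10 rose, 1 fell and 12 did not pass (adjusted over the list alone, 10 rose and 1 fell, list adjusted p = 7.24e-08). RFNR2 (AT1G30510) rose 9.48-fold, G6PD2 7.97-fold and PGD3 (AT5G41670) 7.92-fold. Of 13 genes of ammonium assimilation, 5 rose and 8 did not pass (the same adjusted over the list alone, list adjusted p = 0.00473). The asparagine synthetase gene ASN2 (AT5G65010) rose 9.50-fold and the glutamate synthase gene GLT1 (AT5G53460) 5.34-fold. These 4 lists also passed with an estimated correlation, with adjusted p of 0.00039, 0.00425, 0.00707 and 0.0266.

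Among the 15 auxin response genes, 10 fell, 1 rose and 4 did not pass (adjusted over the list alone, 11 fell and 1 rose, list adjusted p = 5.24e-07, and 0.012 with an estimated correlation). IAA1 fell 2.27-fold, GH3.1 2.02-fold and IAA3 1.87-fold, whereas SAUR15 rose 2.56-fold. Of 12 class III glutaredoxin genes, 9 rose and 3 did not pass (adjusted over the list alone, 9 rose and 1 fell, list adjusted p = 1.28e-08, adjusted p = 0.06 with an estimated correlation). GRXS3, GRXS4, GRXS5, GRXS7 and GRXS8 are near-identical in sequence, so that their probes can bind each other's transcripts. Of 18 genes of cytokinin synthesis and response, 10 rose, 2 fell and 6 did not pass (adjusted over the list alone, 12 rose and 5 fell, list adjusted p = 2.16e-05, adjusted p = 0.0511 with an estimated correlation). IPT3 (AT3G63110), a cytokinin synthesis gene, rose 5.98-fold and the response regulator gene ARR5 2.66-fold.

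Lists called at the preset correlation and not with an estimated correlation were sulphur assimilation (up, adjusted p = 0.00473, adjusted p = 0.187 with an estimated correlation), the NLP family (down, 0.00836, adjusted p = 0.228), low energy response (up, 0.0104, adjusted p = 0.38), touch and early stress (down, 0.0104, adjusted p = 0.38), cell cycle (down, 0.0148, adjusted p = 0.34) and ribosome biogenesis (down, 0.0172, adjusted p = 0.263). In the sulphur list, 5 of 15 genes rose and 2 fell (adjusted over the list alone, 6 and 2), with SERAT2;1 5.21-fold higher. In the NLP list, 5 of 9 fell and 1 rose, with NLP5 3.32-fold and NLP4 2.46-fold lower. The members that rose in the low energy list were the trehalose-phosphate synthase genes TPS9 and TPS10, at 2.21-fold and 2.66-fold, and ATL8. In the touch list, 5 of 13 fell and 1 rose, and in the ribosome list 4 of 15 fell. In the cell cycle list 2 of 10 fell (adjusted over the list alone, 6 fell). The other lists were not called: phosphate starvation (adjusted p = 0.0587), jasmonate (0.184), root hair (0.232), abscisic acid, osmotic and cold response (0.338), reference genes (0.338), circadian clock (0.447), photosynthetic tissue (0.468), root endodermis and stele (0.468), iron (0.67), seed reserve (0.957) and hypoxia (0.979).

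Lines 14 and 7 were compared with their own 0 h samples to ask which nitrate responses are present when the repressor is expressed. In line 14, BT2 rose 85.0-fold (log2 6.41 ± 0.20), NIA1 70.7-fold (log2 6.14 ± 0.15), SAG21 37.4-fold and NIR1 20.5-fold (log2 4.36 ± 0.09). In line 7, BT2 rose 93.6-fold (log2 6.55 ± 0.20), NIA1 68.7-fold (log2 6.10 ± 0.15), SAG21 37.9-fold and NIR1 19.1-fold (log2 4.25 ± 0.09). BT2 was dim in line 7 at 0 h, with a log2 signal of -5.01, so that the size of its rise there is less certain. G6PD3 rose 9.15-fold in line 14 and 4.63-fold in line 7, and LBD39 1.89-fold and 1.68-fold. AT1G64590 fell in both lines, with log2 changes of -3.25 ± 0.12 and -3.17 ± 0.12. The adjusted p of these changes was 7.89e-06 or lower.

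Regulators of nitrate signalling rose as a list in both lines (16 of 21 rose in line 14, adjusted p = 2.86e-17; 17 rose and 1 fell in line 7, adjusted p = 2.16e-17), as did nitrate uptake and reduction (14 of 21 rose and 1 fell in line 14, adjusted p = 1.35e-13; 12 rose and 1 fell in line 7, adjusted p = 4.92e-14). Glutaredoxins rose (8 of 12 in line 14, adjusted p = 1.11e-13; 10 in line 7, adjusted p = 8.98e-15) and auxin response genes fell (12 of 15 in line 14, adjusted p = 1.34e-08; 9 in line 7, adjusted p = 1.87e-06). The pentose phosphate list rose (9 of 23 in line 14, adjusted p = 4.56e-08; 10 in line 7, adjusted p = 7.36e-08), as did ammonium assimilation (5 of 13 in line 14, adjusted p = 0.0063; 6 in line 7, adjusted p = 0.00172). Adjusted over the list alone, in the order of these 6 lists, 17, 14, 10, 12, 9 and 6 genes changed in the list's direction in line 14 and 17, 12, 11, 10, 10 and 6 in line 7. These 6 lists also passed with an estimated correlation in both lines. Low energy genes rose as a list at the preset correlation, with adjusted p = 0.157 in line 14 and 0.059 in line 7 with an estimated correlation. At the preset correlation 9 lists were called in line 14 and 11 in line 7, so that some called lists are not named here. With an estimated correlation 6 lists were called in each line. In all, limma called 4461 genes in line 14, 2186 higher and 2275 lower, and 4031 in line 7, 1922 higher and 2109 lower. With median scaling more genes were higher than lower, 2407 and 1861 in line 14 and 2072 and 1716 in line 7, as they were with normexp (2013 and 1669, and 1934 and 1879). With slide as a block the counts were 4469 and 3994. Of the genes called in the parental line, 2804 were called in line 14 with the same sign and 19 with the opposite sign, and 2302 and 71 in line 7, where independent calls would give 485.3 and 439.3 of the same sign. Fitting the groups of line 14 alone gave 1790 calls.

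The difference between the lines' and the parental response was tested to ask which nitrate responses are altered. For the mean of both lines, NIGT1.3 had a lower response (adjusted p = 0.000123), but its probe was well above background only in the parental line at 1 h, so that the size of this difference was not measured. NITR2;1 rose by 3.64 on the log2 scale in the parental line and by 1.07 in line 14. Its change of 0.39 ± 0.26 in line 7 did not pass (adjusted p = 0.349). With only the 2 groups of a line fitted, the change did not pass in line 14 (adjusted p = 0.133) and passed in line 7 (adjusted p = 0.0103). The difference of the mean of both lines was -2.90 ± 0.32 (adjusted p = 8.78e-05). AT1G49500 differed by -2.89 ± 0.12 (adjusted p = 6.76e-09) and AT3G54830, an amino acid transporter family gene, by -2.93 ± 0.15 (adjusted p = 5.35e-08). G6PD3 differed by -1.93 ± 0.10 (adjusted p = 5.35e-08), ASN2 by -1.77 ± 0.28 (adjusted p = 0.0021), LBD39 by -1.37 ± 0.09 (adjusted p = 1.31e-06) and UPM1 by -1.04 ± 0.11 (adjusted p = 6.33e-05). CAX7, which fell in the parental line, fell less in the lines, by a difference of 2.15 ± 0.14 (adjusted p = 6.27e-07). NIA1 rose by a larger fold in the lines (log2 difference 1.08 ± 0.18, adjusted p = 0.00281), as did NIA2 (1.04 ± 0.26, adjusted p = 0.0429) and BT2 (0.97 ± 0.24, adjusted p = 0.0371). These larger folds started from lower levels at 0 h, and the levels at 1 h stayed below those of the parental line. The difference of BT2 did not pass with normexp background correction (0.41, adjusted p = 0.509), with the mean of all probes of a gene (0.80, adjusted p = 0.118), or, at an unchanged 0.97, with slide as a block (adjusted p = 0.0621), with a replicate block (adjusted p = 0.0624) or with no filter on dim probes (adjusted p = 0.068). That of NIA2 did not pass with normexp (0.95, adjusted p = 0.0632), with the mean of all probes (0.67, adjusted p = 0.278) or with no filter (adjusted p = 0.0791).

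Regulators of nitrate signalling rose less as a list: 7 of 21 had a lower response, 1 a higher one and 13 did not pass (adjusted over the list alone, 12 lower and 2 higher, list adjusted p = 2.36e-07, and 0.0205 with an estimated correlation). CIPK3 differed by -0.92 ± 0.12 (adjusted p = 0.000447) and NIGT1.4 by -0.99 ± 0.21 (adjusted p = 0.014), while LBD37 (-0.30 ± 0.15, adjusted p = 0.431) did not pass. In the pentose phosphate list, 9 of 23 had a lower response and 1 a higher one (adjusted over the list alone, 10 and 1, list adjusted p = 5.85e-07, and 0.0205 with an estimated correlation). Besides G6PD3, the lower ones included PGD3 (-1.10 ± 0.12), RFNR2 (-1.05 ± 0.12) and G6PD2 (-1.03 ± 0.10), and PGL1 was the higher one (0.64 ± 0.14). Of the 18 cytokinin genes, 6 had a lower response (adjusted over the list alone, 9 lower and 1 higher, list adjusted p = 4.12e-05, adjusted p = 0.0887 with an estimated correlation), including ARR15 (-0.98 ± 0.20) and ARR5 (-0.61 ± 0.16), whereas IPT3 (-0.35 ± 0.24, adjusted p = 0.612) did not pass. Of 21 genes of nitrate uptake and reduction, 5 had a lower and 4 a higher response (adjusted over the list alone, 10 and 4, list down, adjusted p = 0.0234, adjusted p = 0.36 with an estimated correlation). The lower ones were NIR1 (-0.46 ± 0.11), NRT3.1 (-0.78 ± 0.10), NRT2.2, UPM1 and NITR2;1, and the higher ones NIA1, NIA2, NRT2.5 and NRT1.2. With normexp NRT2.2 (-0.55, adjusted p = 0.349) and NRT2.5 (-0.11, adjusted p = 0.853, the opposite direction) did not pass, and NIR1 did not pass with quantile normalization (-0.37, adjusted p = 0.0936). The probe of NRT2.2 was well above background only in the parental line at 1 h, and that of NRT2.5 on no array of that group. NRT2.1 differed by -0.35 ± 0.17 (adjusted p = 0.407).

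In the NLP list, 4 of 9 genes had a higher response (adjusted over the list alone, 4 higher and 1 lower, list adjusted p = 7.32e-05, adjusted p = 0.0968 with an estimated correlation). They were NLP4 (0.79 ± 0.10), NLP5 (1.00 ± 0.10) and NLP7 (0.32 ± 0.06), which fell in the parental line, and NLP6 itself, measured by the probe that detects the transgene. Without NLP6, an alternative chosen after the data were seen, the list had an adjusted p of 0.00723, and 0.329 with an estimated correlation. The touch list was up (2 of 13, adjusted over the list alone 5, adjusted p = 7.32e-05, adjusted p = 0.287 with an estimated correlation), with a median difference of 0.33, and the genes that passed were TCH4 (1.15 ± 0.23) and WRKY40 (0.72 ± 0.17). Phosphate starvation was up (2 of 11, adjusted over the list alone 2, adjusted p = 0.0234, adjusted p = 0.0887 with an estimated correlation), where SPX1 (0.61 ± 0.10) and PS2 (0.57 ± 0.14) passed. Sulphur assimilation was down (2 of 15, adjusted over the list alone 2 lower and 1 higher, adjusted p = 0.0234, adjusted p = 0.36 with an estimated correlation), where SERAT2;1 (-0.97 ± 0.11) and SULTR1;2 (-0.50 ± 0.12) passed. The glutaredoxin list was up (1 of 12, adjusted over the list alone 2, adjusted p = 0.0265, adjusted p = 0.572 with an estimated correlation), with a median difference of 0.25, and GRXC14 (0.69 ± 0.15) passed. Of these lists, phosphate starvation and glutaredoxins were called in line 7 (adjusted p = 0.0102 and 0.0386) and not in line 14 (0.173 and 0.0854), whereas uptake and reduction and sulphur assimilation were called in line 14 (0.0157 and 0.00214) and not in line 7 (0.0545 and 0.161). With an estimated correlation these 4 calls were lost (adjusted p = 0.0585, 0.603, 0.266 and 0.2), and the test of line 7 minus line 14 called none of the 4 lists (adjusted p = 0.217, 0.798, 0.925 and 0.217). With slide as a block PS2, WRKY40, ARR5 and NIR1 did not pass, with unchanged differences and adjusted p of 0.0532, 0.0672, 0.0604 and 0.0545. With no filter on dim probes these 4 genes did not pass either, with adjusted p of 0.0724, 0.0511, 0.0793 and 0.0559. With the mean of all probes of a gene PS2 (0.51, adjusted p = 0.269) and WRKY40 (0.76, adjusted p = 0.0522) did not pass.

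**Figure D2:**
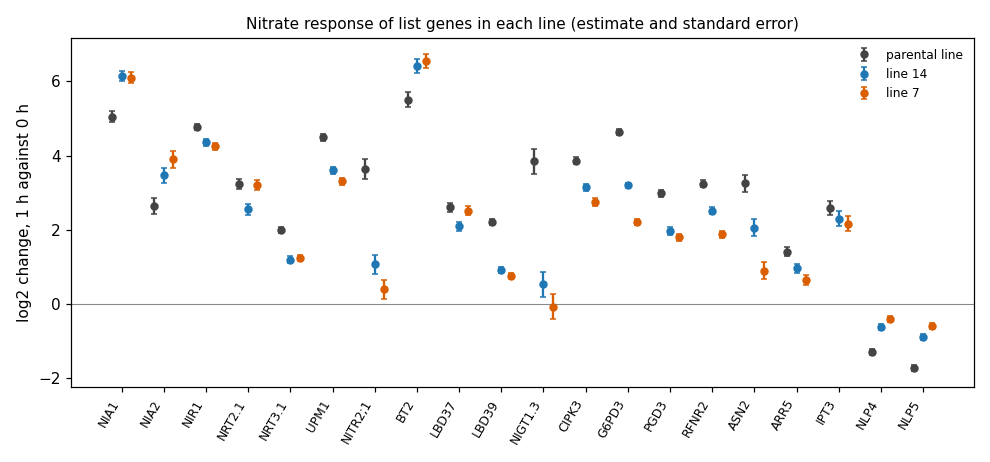
Log2 change at 1 h against 0 h, with its standard error, of 20 list genes in the parental line, line 14 and line 7, with 3 arrays in each group. G6PD3 rose by 4.63 in the parental line, 3.19 in line 14 and 2.21 in line 7, and NIA1 by 5.04, 6.14 and 6.10.

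For the mean of both lines limma called 770 genes, 492 with a higher and 278 with a lower response, for line 14 alone 244 (146 higher, 98 lower) and for line 7 alone 901 (570 higher, 331 lower). Of the 338 genes that rose at least 2-fold in the parental line, 137 rose less in the lines, 6 rose more and 195 did not pass. Of the 269 that fell at least 2-fold, 112 fell less, none fell more and 157 did not pass. These sets were chosen with the same parental arrays that enter the difference. With genes chosen and measured on different parental arrays, line 14 kept 75.4% of the parental rises (75.01% to 75.7% over 3 turns) and line 7 kept 66.1% (65.5% to 66.5%). Of the falls, line 14 kept 63.1% (57.7% to 66.8%) and line 7 kept 46.3% (42.2% to 49.3%). These ranges hold only the spread of the parental arrays. With only the line's arrays of the replicate number left out, rises kept were 72.7% to 77.9% in line 14 and 62.9% to 69.6% in line 7. Falls kept were then 54.1% to 71.5% in line 14 and 42.6% to 51.0% in line 7.

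Of the genes with an altered response, 208 were called in both lines, 120 higher and 88 lower, 0 with opposite signs, where independent calls would give 5.3 of the same sign. The differences of both lines correlated across genes with r of 0.691 and a covariance of 0.0628, and simulated groups that share the parental arrays gave 0.498 and 0.0246. The simulated groups had 0 shared calls, but with no gene changed this was to be foreseen and does not bound the excess from shared arrays. Part of the excess may come from the shared arrays, which were not split between the lines. With slide as a block limma called 732 genes for both lines, 242 for line 14 and 852 for line 7. On slides 1, 2 and 3 the median response difference of the nitrate regulators in line 14 was -0.47, -0.23 and -0.43. The count of line 14 was 126 when its own and the parental groups were fitted alone, 635 without its first replicate at 0 h and 162 without its first replicate at 1 h. Of the 126 genes, 60 had a higher and 66 a lower response, so that the majority turned.

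The lines were compared with the parental line at 0 h to ask which transcripts differ before nitrate is given. Besides SUP and NLP6, the higher genes included the beta-glucosidase gene BGLU28 (AT2G44460), at least 2.49-fold higher in line 14 and at least 18.9-fold in line 7, the sugar transporter genes SWEET10 (9.55-fold for the mean of both lines, log2 3.26 ± 0.19) and SWEET13 (8.43-fold), and UMAMIT19 (8.50-fold), from a family of amino acid transporters. NRT2.5, the gene of a high-affinity nitrate transporter of starved plants, was 6.83-fold higher (log2 2.77 ± 0.11). The lower genes included AT1G47980 (log2 -4.04 ± 0.34), LEA3 (AT1G02820, -3.93 ± 0.27), BT2 (-3.87 ± 0.17) and EARLI1 (AT4G12480, -3.24 ± 0.21). NIA1 was 7.05-fold and NIA2 7.17-fold lower, and NIR1 2.06-fold lower. The adjusted p of these differences of the mean of both lines was 6.08e-07 or lower. The mean holds line 7, for which line and slide cannot be told apart. Its p-values measure the spread between arrays and not the spread between the lines. The lines differed in size: in line 14 and line 7, NIA1 was 5.01-fold and 9.92-fold lower, NIA2 2.86-fold and 17.9-fold, NIR1 1.67-fold and 2.53-fold, and BT2 5.46-fold and 39.3-fold. BT2 was dim in line 7, with a log2 signal of -5.01, so that the size of its difference there is less certain. The log2 differences were -2.31 and -5.77 for AT1G47980, -2.78 and -5.08 for LEA3, and 1.90 and 4.28 for UMAMIT19.

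Ribosome biogenesis genes were lower at 0 h (12 of 15, none higher, the same adjusted over the list alone, list adjusted p = 7.91e-06, adjusted p = 0.131 with an estimated correlation), with FIB1 at -0.59 ± 0.08 and PES at -0.51 ± 0.06. In line 14 alone, 13 were lower and the list passed with an estimated correlation (adjusted p = 5.4e-09, and 0.0368 with it). Of the nitrate regulators, 11 of 21 were lower and 2 higher (adjusted over the list alone, 11 and 3, list adjusted p = 0.000207, adjusted p = 0.131 with an estimated correlation), with CIPK3 3.52-fold and LBD37 2.64-fold lower. Of the uptake and reduction genes, 11 of 21 were lower and 5 higher (adjusted over the list alone, 12 and 5, list adjusted p = 0.0168, adjusted p = 0.349 with an estimated correlation); the higher ones included NRT2.4 (2.77-fold) and NRT2.6 (3.17-fold). The NLP list was higher (7 of 9, adjusted p = 0.000558, adjusted p = 0.269 with an estimated correlation), with NLP3 2.43-fold and NLP8 1.77-fold, and with NLP6, read by the transgene probe, among the 7. Without NLP6, which was chosen after the data were seen, 6 of 8 were higher (adjusted p = 0.011, and 0.349 with an estimated correlation). The touch list was lower (9 of 13, adjusted over the list alone 10, adjusted p = 0.000277, adjusted p = 0.349 with an estimated correlation), with WRKY40 2.50-fold lower. Cytokinin genes were lower (10 of 18, 3 higher, adjusted p = 0.0171, adjusted p = 0.349 with an estimated correlation), as were glutaredoxins (7 of 12, 3 higher, adjusted p = 0.0249, adjusted p = 0.575 with an estimated correlation), while GRXS9 was 4.08-fold higher. Adjusted over the list alone, 7 of the NLP genes were higher, 10 of the cytokinin genes lower and 4 higher, and 8 of the glutaredoxins lower and 3 higher. Sulphur assimilation was higher (9 of 15, 2 lower, adjusted over the list alone 11 and 2, adjusted p = 0.0231, adjusted p = 0.349 with an estimated correlation), with LSU1 3.29-fold and SULTR1;1 2.75-fold. In line 14, which shares slides with the parental line, the regulator and touch lists were also called (adjusted p = 0.000408 and 8.23e-05), but not with an estimated correlation (adjusted p = 0.18 and 0.375). Uptake and reduction (0.116), NLP (0.0937), cytokinin (0.116), glutaredoxins (0.146) and sulphur (0.146) were not called there, and were called in line 7 (adjusted p = 0.015, 0.000754, 0.015, 0.0209 and 0.0252), where none of the 5 passed with an estimated correlation (adjusted p = 0.408, 0.363, 0.408, 0.542 and 0.458).

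At 0 h limma called 10076 genes for the mean of both lines (5543 higher, 4533 lower), 7621 for line 14 (4130 and 3491) and 12792 for line 7 (6954 and 5838). At least 2-fold were 223 higher and 263 lower in line 14 and 785 higher and 933 lower in line 7. Line 7 was on other slides and another scan day than the parental line, so that line and slide cannot be told apart in its count or in its lists. The count and lists of the mean of both lines hold line 7 and share this limit. In line 7 more genes were lower than higher with normexp (6707 and 5841), median scaling (6495 and 5992) and no filter on dim probes (9068 and 6824). Line 14 shared slides with the parental line: with slide as a block 7684 genes were called, and fitting these groups alone gave 3015 calls. The median difference of the ribosome biogenesis genes was -0.49, -0.46 and -0.35 on slides 1, 2 and 3. The lines shared 4056 calls of the same sign and 805 of opposite sign, where independent calls would give 2271.2 of the same sign. The covariance of 0.144 stood against 0.0122 in simulated groups that share the parental arrays, and r of 0.564 against 0.493.

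At 1 h the lines were compared with the parental line to ask which levels differ after nitrate. NIA1 was 3.34-fold, NIA2 3.48-fold, NIR1 2.84-fold and BT2 7.46-fold lower for the mean of both lines. In line 14 and line 7, NIA1 was 2.34-fold and 4.76-fold lower, NIA2 1.62-fold (adjusted p = 0.0197) and 7.50-fold, NIR1 2.23-fold and 3.61-fold, and BT2 2.92-fold and 19.1-fold. LBD39 was 5.04-fold (log2 -2.33 ± 0.07), CIPK3 6.64-fold (log2 -2.73 ± 0.09) and G6PD3 4.32-fold lower (log2 -2.11 ± 0.07) for the mean of both lines. The sulphate transporter family gene SULTR3;5 was at least 4.79-fold lower in line 14 and at least 10.2-fold in line 7. AT1G49500 and AT5G26200, both among the largest rises of the parental line, were 20.4-fold and 19.7-fold lower. Higher genes included NRT2.5 (at least 7.21-fold in line 14 and at least 10.8-fold in line 7), UMAMIT14 (12.9-fold, log2 3.69 ± 0.13) and NLP4 and NLP5 (2.56-fold and 2.62-fold). The adjusted p of the differences of the mean of both lines was 3.98e-06 or lower. This mean also holds line 7, whose slides were not those of the parental line, and its p-values do not measure the spread between the lines.

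Of the 21 nitrate regulators, 15 were lower at 1 h and 2 higher (the same adjusted over the list alone, list adjusted p = 8.08e-07, adjusted p = 0.0538 with an estimated correlation), and in line 14 alone the list passed with an estimated correlation (adjusted p = 3.14e-09, and 0.0124 with it). Ribosome biogenesis genes were lower (14 of 15, adjusted p = 5.23e-06, adjusted p = 0.0839 with an estimated correlation), as were cytokinin genes (13 of 18, 1 higher, adjusted p = 1.97e-05, adjusted p = 0.0842 with an estimated correlation), uptake and reduction genes (15 of 21, 3 higher, adjusted p = 0.000402, adjusted p = 0.0983 with an estimated correlation) and the pentose phosphate list (12 of 23, 6 higher, adjusted p = 0.0257, adjusted p = 0.198 with an estimated correlation). The NLP list was higher (8 of 9, with NLP6, read by the transgene probe, among the 8, adjusted p = 4.42e-05, adjusted p = 0.0983 with an estimated correlation), as was phosphate starvation (7 of 11, 1 lower, adjusted p = 0.0487, adjusted p = 0.0983 with an estimated correlation). Adjusted over the list alone, these counts were the same, except 4 higher uptake and reduction genes and 8 higher phosphate genes. Without NLP6, 7 of 8 NLP genes were higher (adjusted p = 0.000828, and 0.178 with an estimated correlation). The pentose phosphate list was not called in line 14 (adjusted p = 0.0849) and was called in line 7 (0.00766), and phosphate starvation was called in line 14 (0.00703) and not in line 7 (0.145). Both calls were lost with an estimated correlation (adjusted p = 0.164 and 0.0574). The other 5 lists were called in both lines. With an estimated correlation the regulator and ribosome lists passed in line 14 (adjusted p = 0.0124 for both), while cytokinin (0.0664), uptake and reduction (0.149) and NLP (0.125) did not, and in line 7 none of the 5 passed (adjusted p between 0.148 and 0.296). Lists of tissue markers were also called in single lines at 1 h. Photosynthetic tissue markers were lower in line 7 (15 of 19, 2 higher, the same adjusted over the list alone, list adjusted p = 0.000969, adjusted p = 0.436 with an estimated correlation). In line 14 the root hair list (8 of 11, adjusted over the list alone 8, adjusted p = 0.00443, adjusted p = 0.292 with an estimated correlation) and the endodermis and stele list (6 of 11, adjusted over the list alone 7, adjusted p = 0.0179, adjusted p = 0.496 with an estimated correlation) were higher. In all, limma called 11412 genes for the mean of both lines (6153 higher, 5259 lower), 7594 for line 14 (4106 and 3488) and 13836 for line 7 (7311 and 6525), with 7727 for line 14 with slide as a block. More genes were lower than higher with median scaling, 5813 and 5407 for the mean of both lines and 7486 and 6187 for line 7, and in line 7 also with normexp (7205 and 6379) and no filter on dim probes (9495 and 7204). With parental rises chosen and measured on different parental arrays, their median difference at 1 h was -0.67 in line 14 (-0.69 to -0.64 over 3 turns) and -0.96 in line 7 (-0.98 to -0.92), and at 0 h -0.22 and -0.41. The lines shared 5243 calls of the same sign and 409 of opposite sign, where independent calls would give 2441.2 of the same sign. The covariance of 0.20 stood against 0.0123 in simulated groups, and r of 0.667 against 0.504.

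**Figure D3:**
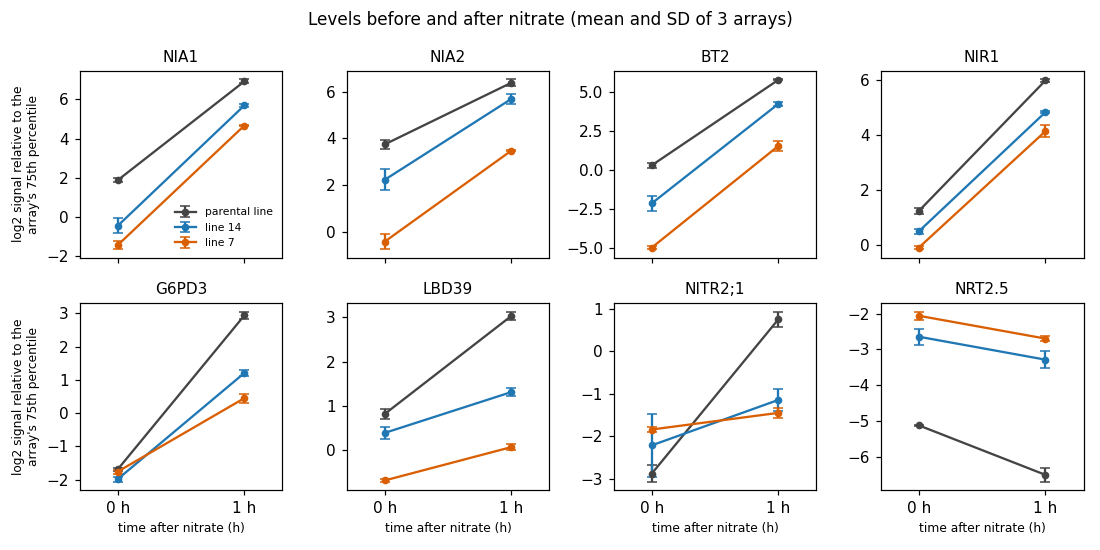
Mean log2 signal relative to the array's 75th percentile, with the SD of 3 arrays, at 0 h and 1 h for NIA1, NIA2, BT2, NIR1, G6PD3, LBD39, NITR2;1 and NRT2.5 in the 3 lines. At 0 h NIA1 was 5.01-fold lower in line 14 and 9.92-fold in line 7, and BT2 5.46-fold and 39.3-fold, and NRT2.5 was higher in the lines at both times. BT2 was dim in line 7 at 0 h, at -5.01.

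The responses of lines 7 and 14 were compared with each other to ask whether the independent lines differ. G6PD3 rose by less in line 7 (log2 difference -0.98 ± 0.11, adjusted p = 0.00163), as did AT1G49500 (-1.14 ± 0.13), and ACD6 (AT4G14400), a defence-related gene, differed by -1.64 ± 0.14. The blue copper-binding protein gene BCB (AT5G20230) differed by 1.55 ± 0.21 and CAX7 by 1.18 ± 0.16. AT2G21210 also had a lower response in line 7 (adjusted p = 0.000141), but its probe was well above background on no 0 h array of either line, so that the size of this difference was not measured. In all, limma called 13 genes, 7 with a higher and 6 with a lower response in line 7, and 17 with slide as a block. The pentose phosphate list was lower in line 7 (1 of 23, adjusted over the list alone 2 lower and 1 higher, adjusted p = 0.021, adjusted p = 0.556 with an estimated correlation, and 0.0529 with slide as a block). With the mean of all probes of a gene the difference of AT1G49500 was -0.77 (adjusted p = 0.408). The count was 141 without the first replicate of line 14 at 0 h, 25 without its second, and 23 without the second replicate of line 7 at 1 h.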

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

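Chosen only after the results were seen were the tests of probes without a locus, of array scaling, of the NLP6 and SUP transcripts, of slide and scan day, of GC content and signal, of clock phase and of compression, the readings of background subtraction for NIA1 and NIA2 alone, and the counts of other splits. The first group of results stands out because the nitrate response differed between lines, tested as a difference of responses with limma. The response of the mean of both lines differed from the parental one in 770 genes, that of line 14 in 244 and that of line 7 in 901, and lines 7 and 14 differed from each other in 13. Among the gene lists, response differences of the mean of both lines were called for regulators of nitrate signalling (adjusted p = 2.36e-07), the pentose phosphate list (5.85e-07), cytokinin (4.12e-05), the NLP family (7.32e-05), touch and early stress (7.32e-05), nitrate uptake and reduction (0.0234), phosphate starvation (0.0234), sulphur assimilation (0.0234) and class III glutaredoxins (0.0265). With an estimated correlation the first 2 of these lists passed (adjusted p = 0.0205 for both), and the other 7 did not, with adjusted p of 0.0887, 0.0968, 0.287, 0.36, 0.0887, 0.36 and 0.572 in this order. The pentose phosphate list also differed between lines 7 and 14 (adjusted p = 0.021), but not with an estimated correlation (adjusted p = 0.556) or with slide as a block (adjusted p = 0.0529). The second group is signal in data that the comparisons of genes do not use: of 2307 tested probes without a locus, 211 were called for the parental nitrate response, 111 higher and 100 lower, and 27 for the response difference of the mean of both lines.

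The upstream NLP6 probe rose by more after nitrate than in the parental line, by 1.48 in line 14 and 1.06 in line 7, and the SUP probe rose with it. Array scaling was argued against, since the median change of the reference genes was 0.009 in line 14 and 0.06 in line 7. The plant's own NLP6 transcript was argued against by the downstream probe, which changed by -0.09 in line 14 and by -0.049 in line 7. The SUP probe rose by 1.502 and 1.179, so that a rise of the transgene transcript itself is a hypothesis with the values it needs. Whether synthesis or stability of the transcript changed was not tested.

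More genes differed from the parental line in line 7 than in line 14. A trend with probe GC content and signal was argued against, since after its removal 12443 genes were called in line 7 and 7792 in line 14 at 0 h. Slide and scan day cannot be told apart from the line: slide 5 against slide 4 within line 7 gave 0 calls by limma, with 1654 genes at an unadjusted p under 0.05, and this compares slides of the same scan day only. Clock phase at harvest is a hypothesis for part of the difference, since morning-phased clock genes had a median difference of -2.251 and evening-phased ones of 0.695 in line 7 at 0 h, against -0.41 and 0.021 in line 14. Whether clock phase extends to the other genes was not tested, and a stronger effect of the transgene in line 7 stays open and untested.

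NIA1, NIA2 and BT2 rose by a larger fold in the lines than in the parental line, from lower levels at 0 h. The test of background subtraction set before the data were seen took the lowest difference of the 3 with normexp. It was 0.412, between the limits set, and did not decide. In readings of single genes chosen afterwards, background subtraction of dim signals was argued against for NIA1, whose difference was 1.079 ± 0.178 and 1.014 ± 0.164 with normexp (adjusted p = 0.00165). It was also argued against for NIA2 by size, with 1.041 ± 0.26 and 0.951 ± 0.259, although the call ended at an adjusted p of 0.0632. It stays open for BT2, whose difference fell to 0.412 ± 0.216 (adjusted p = 0.509). With the mean of all probes of a gene, the calls of NIA2 (0.672, adjusted p = 0.278) and BT2 (0.802, adjusted p = 0.118) also ended. With slide as a block the difference of BT2 stayed at 0.974, with an adjusted p of 0.0621. Compression of bright signals in the parental line at 1 h also stays open: the other induced genes at least as bright were 3, with a median difference of -0.464 and an upper quartile of 0.05. None of the 3 genes was saturated on any array.

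Other splits of the same arrays were counted on 21548 genes with a value on every array, with only the arrays compared in the fit. Where the mean of both lines was compared, lines 14 and 7 were pooled into 1 group for these counts, so that differences between them entered the spread. The real counts are then lower than with a mean for each line, where fits of the compared groups gave 770 for the response difference, 8409 at 0 h and 11896 at 1 h. For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05, and 1 split, the real one, called as many genes. The real and highest other counts were 3571 and 0 for the parental nitrate response, 1778 and 1 for line 14, and 5282 and 0 for line 7. They were 3004 and 0 for line 14 and 12887 and 0 for line 7 against the parental line at 0 h, and 6800 and 0, and 13900 and 0, at 1 h. For the response difference of the mean of both lines, 3 of 100 splits called as many as the real 98, the highest other 191. For line 14 these were 4 of 100, 126 and 573, for line 7 4 of 100, 1016 and 8082, and for line 7 minus line 14 3 of 100, 13 and 6064. A split that mixes the lines puts their level differences into its spread and so calls few genes. These shares therefore cannot tell whether the response differences arose by chance. Splits that call many more genes point to the structure of the samples: they keep a line together at one time, so that differences between lines enter. In the fit of all 18 arrays with a mean for each group, these 4 response differences had 770, 244, 901 and 13 calls, and 732, 242, 852 and 17 with slide as a block. For the mean of both lines against the parental line, 2 of 84 splits called as many as the real 2898 at 0 h and 5446 at 1 h. The highest others, 9854 and 11263, set line 7 against the rest, where line, slide and scan day cannot be told apart. For line 14, which shares slides with the parental line, a slide block in the fit of all 18 arrays gave 7684 calls at 0 h and 7727 at 1 h, against 7621 and 7594 without it.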

How the results depend on the processing

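Of the recomputed counts of genes, 303 stayed within 1.5 times and 46 did not. Of the shares of the response kept, 17 moved by less than the SD over the 3 turns and 15 by more. That SD holds the spread of the parental arrays and not that of the lines. Of the counts of called lists, 35 stayed within 1.5 times and 13 did not. The cause of a change was not tested except where fewer samples or a stricter fold entered by construction. With a minimum of 2-fold the counts were, by construction, 607, 400 and 358 for the nitrate response of the parental line, line 14 and line 7, 132, 62 and 213 for the response differences of both lines, line 14 and line 7, 810, 486 and 1718 at 0 h, 1072, 629 and 2204 at 1 h, and 8 for line 7 minus line 14. With only the compared groups, and so fewer samples, they were 1790 for the nitrate response of line 14, 126 for its response difference and 3015 for its comparison at 0 h. Without the line 7 arrays, an alternative chosen after seeing the data, the response difference of line 14 was also 126. In both fits 60 of these genes had a higher and 66 a lower response. Line 7 minus line 14 had 29 calls with normexp, 26 with quantile normalization, 42 with an intensity trend and 22 with a replicate block. With replicates left out, and so fewer samples, the ranges were 2913 to 4118 for the parental nitrate response, 2656 to 6298 for line 14 and 2035 to 3162 for line 7. For the response differences they were 191 to 1111 for both lines, 91 to 635 for line 14, 295 to 764 for line 7 and 3 to 141 for line 7 minus line 14. Both highest values of line 14 and of line 7 minus line 14 came without the first replicate of line 14 at 0 h, while without its first replicate at 1 h line 14 had 162. At 0 h the ranges were 7523 to 10551 for both lines, 4087 to 9434 for line 14 and 9983 to 12096 for line 7, and at 1 h 8194 to 10927, 4724 to 7038 and 11213 to 13173. The share of parental rises kept by line 14 was 72.1% with normexp, 73.6% with quantile normalization, 74.9% with median scaling, 75.9% with no filter, 76.5% with genes well above background on all arrays, 79.3% with no fold minimum and 74.5% with the GC and signal correction, which was chosen after seeing the data. For line 7 it was 64.1% with normexp, 63.8% with quantile normalization, 68.9% well above background, 70.2% with no fold minimum and 65.5% with that correction. The share of falls kept was 70.5% in line 14 and 54.6% in line 7 with no fold minimum, and 41.2% in line 7 with normexp. With the GC and signal correction more genes were lower than higher at both times, 6293 and 6150 for line 7, 3927 and 3865 for line 14 and 5075 and 4928 for both lines at 0 h, and 7041 and 6523, 4010 and 3713, and 5915 and 5459 at 1 h. With an estimated correlation the called lists dropped from 13 to 5 for the parental nitrate response, from 11 to 6 for line 7, from 9 to 2, 7 to 2 and 7 to 2 for the response differences, from 8 to 0, 4 to 1 and 11 to 0 at 0 h, from 7 to 0, 8 to 2 and 7 to 0 at 1 h, and from 1 to 0 for line 7 minus line 14, which also had 0 with slide as a block, chosen after seeing the data. The 40 recomputed values of the NLP6 probes kept direction and side of the threshold. For the named genes, 168 changes were recomputed in 4637 values: 4428 kept their side of the threshold, 205 lost the call (67 with a replicate number and 80 with a single array left out) and 3 gained it, and 1 turned, the response difference of NRT2.5 with normexp (-0.112, adjusted p = 0.853). Direction was compared only where the main or the recomputed value passed. Dim signals limit what can be seen, since at most 75.1% of spots on an array were well above background. Slide as a fixed block could not be estimated for line 7 against the parental line and for the mean of both lines against it.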

Other observations

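The test of clock phase used here was chosen only after the values were seen. At 0 h, GLN1;4, a cytosolic glutamine synthetase gene, was 2.86-fold higher (log2 1.51 ± 0.12, n = 3 arrays per group) and SDI1, a gene induced by sulphur shortage, 2.21-fold higher (log2 1.15 ± 0.15) for the mean of both lines (SDI1 in line 14 alone adjusted p = 0.097), while GLN2, the plastid form, was 1.94-fold lower (log2 -0.96 ± 0.06). The ammonium assimilation list was not called (4 of 13 genes higher, 3 lower, adjusted p = 0.876). ADH1, an alcohol dehydrogenase gene, was 2.52-fold lower (log2 -1.33 ± 0.15). The late seed genes EM6 and PER1 were 6.81-fold and 7.30-fold lower (adjusted p = 0.00949 and 0.00546, and 0.0532 and 0.0774 in line 14 alone), whereas the seed reserve list did not pass (4 of 12 genes higher, 2 lower, list adjusted p = 0.762, median 0.52 and mean -0.068). In line 14 alone the root hair list was higher (8 of 11, adjusted p = 0.0104, adjusted p = 0.464 with an estimated correlation), with EXPA7 1.65-fold and LRX1 1.62-fold (adjusted p = 0.0026, and 0.0569 with only the compared groups fitted), and the SADHU3-2 element was 10.1-fold higher. In line 7 alone, FMO1, a gene of systemic defence, was at least 10.3-fold higher, and BCB and the heat shock protein gene HSP17.6A were 26.5-fold and 27.9-fold lower.

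In line 7 at 0 h, 16 of 19 photosynthetic tissue markers were lower and 1 higher (list adjusted p = 0.0005, adjusted p = 0.408 with an estimated correlation), with LHCB2.1 3.92-fold and GUN4 2.21-fold lower. Of 10 cell cycle genes 8 were higher (list adjusted p = 0.0209, adjusted p = 0.501 with an estimated correlation), with CYCD4;1 1.75-fold. The morning clock genes CCA1 and LHY were 5.71-fold and 6.26-fold lower, and the evening genes ELF4 and PRR5 2.47-fold and 1.98-fold higher. In line 14 CCA1 was 1.69-fold lower (adjusted p = 0.0223, 0.0927 with only the compared groups fitted, and 0.0562 without the line 7 arrays, an alternative chosen after seeing the data) and LHY did not pass (adjusted p = 0.119). The medians of 4 morning and 6 evening genes in line 7, -2.251 and 0.695, may reflect another clock phase at harvest, in seedlings grown in continuous light. This stays a hypothesis, since line 7 also differed in slide and scan day. In nitrate, the haemoglobin gene HB1 rose 9.63-fold in the parental line. LBD41, a gene of the hypoxia list, had a response difference of 1.02 ± 0.19 in the mean of both lines (adjusted p = 0.00701, and 0.0717 with normexp). A positive difference can also be a smaller fall. A probe without a locus, described as LBD41, changed on the log2 scale by -3.137 in the parental line, -2.059 in line 14 and -1.117 in line 7.

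The largest parental nitrate changes of probes without a locus were rises of 4.637 ± 0.258 and 4.516 ± 0.097 on the log2 scale (adjusted p = 2.1e-08 and 1.37e-13), chosen after their values were seen. The authors' probe descriptions relate them to an ankyrin repeat protein and to a uroporphyrinogen methyltransferase, the activity that UPM1 encodes. In line 14 these probes rose by 4.11 and 3.735 and in line 7 by 2.607 and 3.232. For the mean of both lines 17 probes had a higher and 10 a lower response.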
